A study of Mus musculus with 20 samples.

How the data were processed

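The series holds RNA sequencing of whole aorta from 20 mice, 5 each of Pparafl/fl and smooth-muscle Ppara knockout at 2 and 28 months. The extraction notes name islets in one place, while the tissue of each sample is aorta. The authors deposited 4 tables of all genes, one per pair of groups, with gene counts for each library, and the same counts for a library in both tables that hold it. Per the labels, HISAT, featureCounts 1.5.0-p3 and DESeq 1.8.3 were used with genome build GRCm38. Group mean columns deposited by the authors are a scaled expression signal, not the plain mean of the counts, and were not analysed. The authors also deposited signed fold changes and p-values of their own test. Their adjusted p-values, as deposited, equal Benjamini-Hochberg values over only the genes already past p 0.05 and 2-fold. With that adjustment over all genes with a p, 107 of the 836 genes they listed for the genotypes at 28 months stay under 0.05, and 200 of the 1082 at 2 months. The values are 1862 of 3269 for age in Pparafl/fl and 1900 of 3246 for age in the knockout.

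Counts were joined to 1 table of 55421 genes. Of these, 55240 identifiers (99.7%) matched GENCODE release M21 on GRCm38, from which coordinates and exon numbers were taken. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each pair of groups was fitted alone in edgeR with TMM scaling, the filterByExpr filter and the two-sided quasi-likelihood F test, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The interaction used all 20 libraries. Standard errors are the log2 fold change divided by the root of F. CPM are scaled within the pair compared, or over 20 libraries where values per library are given. Folds against a group at 0 in each library use a floor of 3 counts over the group, and such floors cover counting error only. Total counts were 50046288 to 79385413 per library. The biological coefficient of variation in the edgeR fits lay between 0.53 and 0.73 over the comparisons, so total counts alone do not set the precision. Xist was at most 1.97 CPM and Ddx3y between 75.8 and 188 CPM in each library, so no term for sex was fitted. No pseudocount choice applied, since the files hold counts.

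Gene lists were fixed before the data were examined: PPARα targets, contractile smooth muscle, extracellular matrix and elastic fibre, matrix proteases and inhibitors, senescence, cell cycle, interferon response, antigen presentation, antioxidant, circadian clock, oxidative phosphorylation, cholesterol synthesis, osteochondrogenic and immediate early genes. Marker lists were macrophage, T and NK cell, B and plasma cell, brown adipocyte, adipocyte, skeletal muscle, cardiomyocyte, endothelial, fibroblast, Schwann and neuronal, erythroid and mesothelial. These 26 lists were tested with camera at a preset correlation of 0.01 and, as an alternative, an estimated one, with adjustment over the lists of a comparison. A list of 18 airway genes was added after the data were seen. Named genes followed a fixed rule: Ppara; the 5 largest rises and falls among called genes whose groups do not overlap, with a mean of at least 50 counts and no clone name; up to 3 members of each called list with the smallest p, or the 2 most abundant where none passed; and the most abundant member of each other marker list. For the interaction the rule names Ppara and up to 5 called genes, of which there were none. Other genes named were chosen after their values were seen. Results for 2 items withheld for evaluation are not reported here.

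Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter, a mean of at least 50 counts, a 2-fold minimum, 1 fit of 20 libraries, an adipocyte covariate and leaving out each library. Fits added after the data were seen left out single-exon and unevenly counted genes, or 9 libraries with Scgb1a1 above 1 CPM. Others used airway, skeletal muscle or contractile means, or a clock contrast, as a covariate. The clock contrast was the log2 mean of Dbp, Per3 and Ciart minus that of Arntl, Npas2 and Clock. A covariate computed from a list says nothing about that same list. The test of scaling, first a change of size factors that moved almost no value, was replaced by 1 on unscaled counts, and the test of the collection hour was widened from 6 clock genes to the list of 19, both after their results were seen. The test of a lower share of smooth muscle cells was written, divided by genotype and, for the knockout, moved from skeletal muscle to macrophage markers after its result was seen. On data simulated from the counts with 200 changed genes, edgeR made between 35 and 93 calls with at most 4 false. DESeq2 made between 141 and 224 calls, of which between 58 and 86 were false, so its higher counts are given beside those of edgeR and not in their place.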

Results

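RNA was sequenced from whole aortas of 20 C57BL/6 mice, 1 library per animal, in 4 groups of 5. Pparafl/fl mice carry a conditional allele of Ppara, the gene of the nuclear receptor PPARα, which drives genes of fatty acid oxidation. The knockout lacks Ppara in smooth muscle cells, as the labels name it. Each genotype was studied at 2 and at 28 months. Total counts lay between 62139325 and 73535552 in Pparafl/fl at 2 months and between 51745250 and 72255110 in the knockout at 2 months. At 28 months they lay between 50046288 and 71172745 in Pparafl/fl and between 58794050 and 79385413 in the knockout. The design asks how the aorta changes with age in each genotype, how the genotypes differ at each age, and whether the age effect differs between genotypes. Values below are CPM (counts per 1e6 counts) after scaling within the groups compared, as mean ± SD.

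Ppara itself, on chromosome 15 (GRCm38, 85734983 to 85802819, 8 exons, ENSMUSG00000022383), was not called different between the genotypes at either age. At 2 months it averaged 102 ± 24.6 CPM (SD, n = 5) in the knockout and 128 ± 41.7 CPM (SD, n = 5) in Pparafl/fl, a log2 fold change of -0.33 with a standard error of 0.25 and an adjusted p of 0.664. At 28 months it averaged 77.0 ± 20.8 CPM (SD, n = 5) in the knockout and 71.2 ± 26.0 CPM (SD, n = 5) in Pparafl/fl, a log2 fold change of 0.11 with a standard error of 0.31 and an adjusted p of 1. On one scale for all 20 libraries, Ppara was 88.9, 148, 191, 156 and 92.2 CPM in Pparafl/fl replicates 1 to 5 at 2 months, and 109, 69.6, 115, 138 and 101.4 CPM in the knockout. At 28 months it was 89.3, 70.5, 25.8, 83.0 and 65.7 CPM in Pparafl/fl and 57.5, 90.8, 71.9, 47.7 and 91.0 CPM in the knockout. With age Ppara had a log2 fold change of -1.02 with a standard error of 0.33 and an adjusted p of 0.106 in Pparafl/fl, and of -0.57 with a standard error of 0.23 and an adjusted p of 0.168 in the knockout. The deleted exon is not stated and whole aorta holds cells other than smooth muscle, so gene-level counts are a limited check of the genotype. RNA of fat was abundant, since Fasn, an adipocyte marker, had the most counts of any gene in each library at 2 months. On the scale of all 20 libraries Fasn averaged 34160 CPM in young Pparafl/fl and 39370 CPM in the young knockout. Acta2, smooth muscle actin, averaged 2282 and 1580 CPM in these groups.

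**Figure D1:**
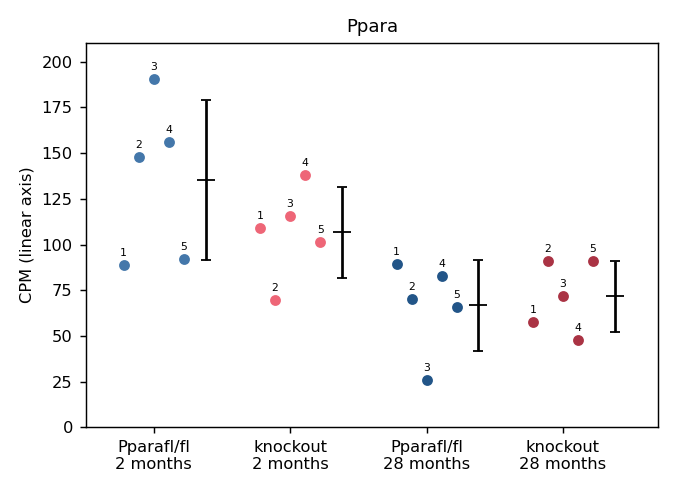
Ppara CPM (linear axis from 0) in each of the 20 libraries, numbered by replicate, with the mean and SD of each group of 5 beside the points. Knockout libraries at 2 months lay between 69.6 and 138 CPM, inside or near the range of 88.9 to 191 CPM in Pparafl/fl.

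The age comparison in Pparafl/fl asks what differs between aortas of 28 and 2 months. Genes of the contractile apparatus and of the extracellular matrix were lower at 28 months. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), fell from 1665 ± 584 CPM (SD, n = 5) to 122 ± 56.9 CPM (SD, n = 5), 13.6-fold. Eln, which encodes elastin (chromosome 5, 134702593 to 134747323), fell from 787 ± 393 CPM (SD, n = 5) to 38.2 ± 11.9 CPM (SD, n = 5), 20.6-fold. Of 20 skeletal muscle markers 3 were higher, and of 15 airway epithelium genes 10, and neither list call held with an estimated correlation (adjusted p = 0.265 and 0.18).

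Of 24 tested contractile smooth muscle genes, 16 fell and 1 rose, and 18 were lower and 2 higher adjusted over the list alone. Tagln, the actin-binding protein transgelin, fell from 631 ± 195 CPM (SD, n = 5) to 34.0 ± 14.2 CPM (SD, n = 5) with an adjusted p of 0.000724. Smtn, which encodes smoothelin, fell by 2.51 on the log2 scale with a standard error of 0.24. The 1 member that rose was Des, the muscle filament protein desmin, also abundant in skeletal muscle. The list had a median log2 fold change of -2.09 and an adjusted p of 2.43e-31 in the gene set test, and an adjusted p = 0.0293 with an estimated correlation. Of 32 extracellular matrix and elastic fibre genes, 26 fell and 0 rose, and 29 were lower adjusted over the list alone. Fn1, which encodes fibronectin, fell from 1271 ± 175 CPM (SD, n = 5) to 203 ± 51.1 CPM (SD, n = 5), and Col1a1, a chain of type I collagen, fell by 4.06 on the log2 scale. The list's median log2 fold change was -2.29, with an adjusted p of 2.51e-63, and an adjusted p = 0.00732 with an estimated correlation. Of 19 matrix proteases and inhibitors, 4 fell, among them Mmp2, Ctsk and Timp1, and 6 were lower and 3 higher adjusted over the list alone. That list had an adjusted p of 0.000501, and an adjusted p = 0.0293 with an estimated correlation. Sost, which encodes sclerostin (chromosome 11, 101962458 to 101967015), fell from 127 ± 49.5 CPM (SD, n = 5) to 0.563 ± 0.436 CPM (SD, n = 5).

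Some fibroblast and adipocyte markers were lower as well, in lists whose calls were lost with an estimated correlation (adjusted p = 0.097 and 0.3). Of 18 fibroblast and adventitia markers 5 fell and 12 were lower adjusted over the list alone, with a median log2 fold change of -1.22. Lum, which encodes the collagen-binding protein lumican, fell 4.55-fold. Of 22 adipocyte markers 3 fell and 4 were lower adjusted over the list alone. Pck1, an enzyme of glycerol and glucose synthesis, fell from 4470 ± 717 CPM (SD, n = 5) to 1706 ± 773 CPM (SD, n = 5). Of 15 brown adipocyte markers 2 fell, Dio2 and Prdm16, also adjusted over the list alone. Of 37 PPARα target genes 1 fell, Pdk4, a kinase that restrains glucose oxidation, with a log2 fold change of -1.78, and 2 were lower adjusted over the list alone. No member of the oxidative phosphorylation, interferon response, antigen presentation or cell cycle lists passed the test, over all genes or adjusted over the list alone. Those lists were called by the preset test with median log2 fold changes of -0.60, -0.42, -0.33 and 0.93. With an estimated correlation the calls were lost: adjusted p = 0.097 for fibroblast markers, 0.3 for both adipocyte lists, 0.439 for PPARα targets, 0.563 for oxidative phosphorylation and 0.676 for the interferon, antigen presentation and cell cycle lists.

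Skeletal muscle markers were higher in 20 of 20 members, with 3 past the test over all genes and 14 adjusted over the list alone. Myh1, a fast skeletal myosin, rose from 15.7 ± 20.7 CPM (SD, n = 5) to 1304 ± 807 CPM (SD, n = 5). Its log2 fold change was 6.38, or 7.23 without replicate 2 at 2 months, and its adjusted p lay between 0.0526 and 0.0707 without any one of the other libraries but replicate 1 at 28 months. The list's median log2 fold change was 3.45, with an adjusted p of 4.1e-15, and an adjusted p = 0.265 with an estimated correlation. Of 21 B and plasma cell markers 5 rose and 0 fell, all immunoglobulin chains or Mzb1, a plasma cell chaperone, and 7 were higher and 4 lower adjusted over the list alone. Igkc, the constant kappa light chain and a single-exon gene at 0 or 1 count in 2 of the 20 libraries, rose from 330 ± 150 CPM (SD, n = 5) to 3222 ± 3503 CPM (SD, n = 5). On one scale for all libraries it was 9257 CPM in replicate 3 at 28 months and between 1020 and 2446 CPM in the other 4. Without that replicate the log2 fold change of Igkc was 2.34 in place of 3.29. Its adjusted p was between 0.0542 and 0.0704 without replicates 2, 3, 4 or 5 at 2 months. Of 15 cardiomyocyte markers 4 rose, also adjusted over the list alone: Myl2, Nppb, Nppa and Myh7. The 5 largest rises named by rule were Cyp2a5, Bpifa1, Spag17, A2ml1 and Cldn8, several of them abundant in airway lining. Cldn8 was at 0 counts in all 5 young libraries and has a single exon, a class of genes often counted unevenly between libraries, as given below. Bpifa1, a secreted airway protein, rose from 0.122 ± 0.23 CPM (SD, n = 5) to 884 ± 1240 CPM (SD, n = 5), a log2 fold change of 12.77, or 11.48 without replicate 2 at 28 months and 15.29 without replicate 5 at 2 months. Cyp2a5 was at 0 counts in all 5 young libraries and between 0.992 and 305 CPM at 28 months. Its adjusted p was 0.0393, and between 0.0606 and 0.0767 without any one library other than replicates 1 and 5 at 28 months. Of 15 airway epithelium genes, a list chosen after the data were seen, 10 rose and 13 were higher adjusted over the list alone. Its adjusted p was 4.65e-13, and its adjusted p = 0.18 with an estimated correlation.

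The other 14 lists were not called, with adjusted p between 0.0505 and 0.946. Their median log2 fold changes were 0.10 for senescence, -0.04 for antioxidant genes, 0.64 for the circadian clock, 0.03 for cholesterol synthesis, -0.34 for osteochondrogenic genes and -0.35 for immediate early genes. Among markers they were 0 for macrophages, 0.13 for T and NK cells, -0.21 for B and plasma cells, 0.14 for cardiomyocytes, -0.09 for endothelium, 0.52 for Schwann cells and neurons, 0.19 for erythroid cells and 0.28 for mesothelium. Members past the test in these lists included Igfbp7 among senescence genes, Nox4 and Prdx1 among antioxidant genes and Klf4, Hsph1 and Dnajb1 among immediate early and heat shock genes, all lower, and Per3 and Tef higher with Npas2 lower in the clock list. These clock genes moved in the direction in which knockout replicates 1 to 4 at 2 months lay from Pparafl/fl. A difference in collection hour between the ages was not tested. The senescence and B cell medians were opposite in sign to the direction of their tests.

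In all, 432 genes rose and 521 fell of 20989 tested by edgeR, and 4775 had an unadjusted p under 0.05 where chance gives 1049. DESeq2 called 1977 higher and 1341 lower. With the skeletal muscle, airway or adipocyte mean as a covariate, edgeR called 6, 44 and 203 genes of either direction. Leaving out replicates 1 to 5 at 2 months in turn gave 150, 266, 155, 132 and 150 higher and 261, 307, 279, 231 and 288 lower. At 28 months the counts were 1019 higher and 1275 lower without replicate 1, 268 and 308 without replicate 4, and 345 lower without replicate 5. In a fit without the 9 libraries that held more than 1 CPM of Scgb1a1, a secretory gene of airway club cells, 15 genes were higher and 25 lower. That fit, chosen after the data were seen, keeps 1 library per genotype at 28 months.

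**Figure D2:**
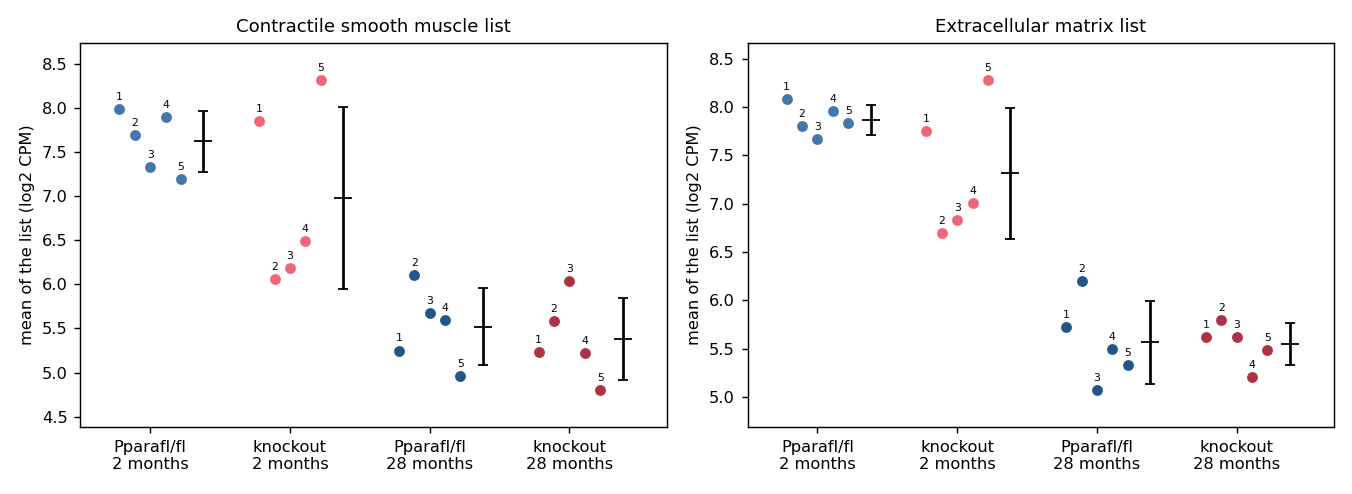
Mean log2 CPM of the contractile smooth muscle list (left) and the extracellular matrix and elastic fibre list (right) in each of the 20 libraries, numbered by replicate, with the mean and SD of each group of 5 beside the points. The contractile mean was 7.20 or more in each Pparafl/fl library at 2 months and 6.11 or less in each library at 28 months.

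The same age comparison in the knockout gave lower values at 28 months in 21 of 32 matrix, 7 of 24 contractile and 21 of 32 oxidative phosphorylation genes and higher ones in 3 of 21 B and plasma cell markers. None of these list calls held with an estimated correlation (adjusted p = 0.167, 0.362, 0.167 and 0.53). Col3a1, the chain of type III collagen (chromosome 1, 45311538 to 45349706), fell from 1617 ± 858 CPM (SD, n = 5) to 162 ± 46.4 CPM (SD, n = 5), 9.99-fold. Acta2, smooth muscle actin, fell from 1607 ± 1770 CPM (SD, n = 5) to 96.8 ± 42.5 CPM (SD, n = 5), a log2 fold change of -4.05 with an adjusted p of 0.0272, or -3.29 with an adjusted p of 0.0556 without replicate 5 at 2 months. The adjusted p of Acta2 was also above 0.05, at most 0.0652, without replicate 1 at 2 months or replicates 1, 2, 3 or 4 at 28 months. Ndufb8, a subunit of respiratory complex I, fell from 186 ± 51.5 CPM (SD, n = 5) to 49.4 ± 13.7 CPM (SD, n = 5). Lyz2, the lysozyme of macrophages, rose from 355 ± 93.6 CPM (SD, n = 5) to 1498 ± 756 CPM (SD, n = 5).

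Of 32 matrix genes 21 fell and 27 were lower adjusted over the list alone, with a median log2 fold change of -1.71. Of 24 contractile genes 7 fell and 21 were lower adjusted over the list alone, with a median of -1.70. Of 32 oxidative phosphorylation genes 21 fell and 29 were lower adjusted over the list alone, with a median of -1.10. Ndufb3, another complex I subunit, fell from 57.9 ± 21.3 CPM (SD, n = 5) to 6.92 ± 2.83 CPM (SD, n = 5). Of 35 PPARα target genes 8 fell and 1 rose, and 21 were lower and 2 higher adjusted over the list alone. Angptl4, a secreted inhibitor of lipoprotein lipase, fell 2.85-fold, and Acaa2, an enzyme of fatty acid oxidation, fell 2.60-fold. Of 18 fibroblast markers 5 fell and 11 were lower adjusted over the list alone, and of 22 adipocyte markers 4 fell and 10 were lower adjusted over the list alone. Of 15 brown adipocyte markers 4 fell, with 5 lower and 2 higher adjusted over the list alone, and Cidea, a lipid droplet protein of brown fat, fell 3.86-fold. Of 18 immediate early and heat shock genes 2 fell, Klf4 and Hsph1, and 5 were lower adjusted over the list alone. With an estimated correlation these calls were lost: adjusted p = 0.167 for the matrix, oxidative phosphorylation, fibroblast and brown adipocyte lists, 0.362 for the contractile and PPARα lists and 0.364 for the adipocyte and heat shock lists.

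Of 21 B and plasma cell markers 3 rose and 5 were higher adjusted over the list alone. Ighg2c, an immunoglobulin heavy chain, rose from 8.98 ± 7.08 CPM (SD, n = 5) to 1119 ± 1475 CPM (SD, n = 5), a log2 fold change of 6.96, or 5.69 without replicate 4 at 28 months. Of 20 macrophage markers 1 rose, Lyz2, and 2 were higher adjusted over the list alone. No cell cycle gene passed over all genes, and 22 of 31 were higher adjusted over the list alone, with a median log2 fold change of 1.77. The cell cycle mean was 5.18, 4.03 and 3.63 log2 CPM in replicates 1, 4 and 5 at 28 months. Replicates 2 and 3, at 2.22 and 2.37, lay inside the young knockout range of 1.73 to 2.93. No T and NK cell marker and no antigen presentation gene passed in either way, with list medians of 0.90 and 0.61. With an estimated correlation these 5 calls were lost too: adjusted p = 0.53 for B and plasma cells, 0.552 for macrophages, 0.562 for the cell cycle, 0.67 for T and NK cells and 0.74 for antigen presentation. Of 18 airway genes 6 rose and 16 were higher adjusted over the list alone, with an adjusted p of 1.3e-13, and an adjusted p = 0.271 with an estimated correlation. Skeletal muscle markers had a median log2 fold change of 0.43 and were not called. The other lists not called had adjusted p between 0.0641 and 0.762, and the antioxidant list's median of 0.10 was opposite in sign to its test.

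The largest falls named by rule were Prnd, Mfap4, Itga8, Map3k7cl and Adra1d, the last an adrenergic receptor of smooth muscle. The largest rises were Upk3a, a urothelial protein, and the single-exon genes Mblac1, Tmem158, Hist2h3c2 and Olfr1034, each at 0 counts in all 5 young knockout libraries. Such genes were often at 0 or 1 count in some libraries and high in others: 177 of 187 single-exon protein-coding genes with at least 500 counts in 2 libraries were, against 231 of 12627 with several exons. In all, 391 genes rose and 543 fell of 20950 tested by edgeR, and 4794 had an unadjusted p under 0.05 where chance gives 1048. DESeq2 called 1911 higher and 1530 lower. With the adipocyte marker mean as a covariate 8 were higher and 2 lower, with the airway gene mean 0 and 1, and in the fit without the 9 libraries above 7 and 9. Leaving out replicates 1 to 5 at 2 months in turn gave 186, 242, 135, 89 and 93 higher, and 246, 273, 146 and 162 lower without replicates 1, 3, 4 and 5. Leaving out replicates 1 to 4 at 28 months gave 197, 132, 131 and 157 higher and 343, 208, 192 and 240 lower.

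**Figure D3:**
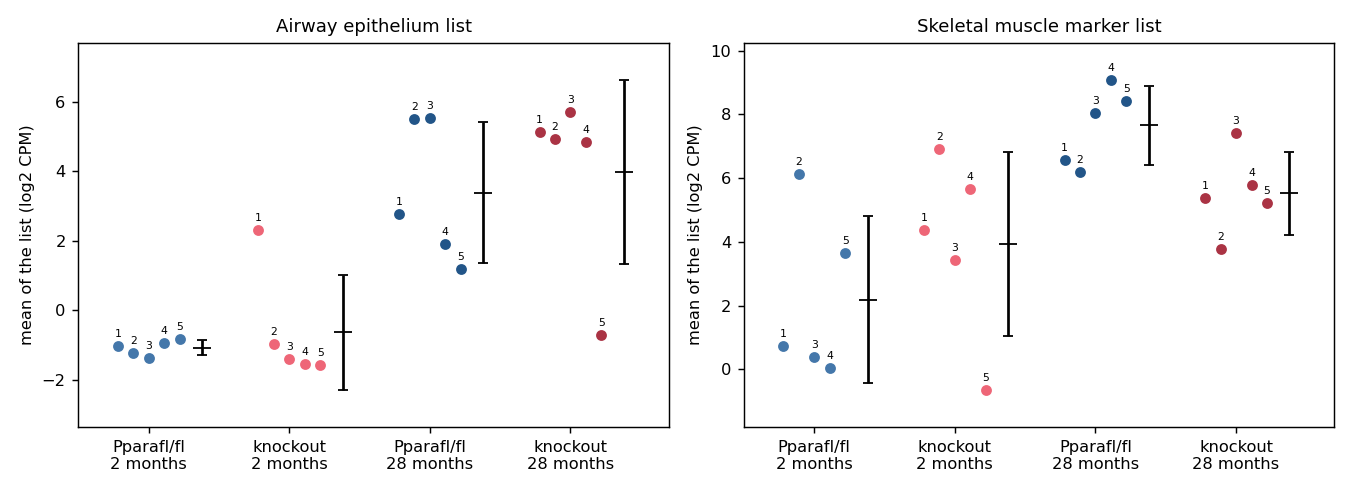
Mean log2 CPM of the airway epithelium list (left) and of the skeletal muscle marker list (right) in each of the 20 libraries, numbered by replicate, with the mean and SD of each group of 5 beside the points. The airway mean was -0.73 in knockout replicate 5 at 28 months, and between 4.85 and 5.70 in the other knockout libraries of that age.

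The genotype comparison at 2 months asks what loss of Ppara in smooth muscle changes in the young aorta. Knockout replicates 1 to 4 lay outside the Pparafl/fl range, all on 1 side of it, in 10 of the 19 genes of the circadian clock list. In these 10 genes replicate 5 lay inside that range in 8, with the other knockout libraries in 1, Nr1d1, and on the opposite side in 1, Ciart. Of 19 circadian clock genes none passed over all genes, and 6 were higher and 1 lower adjusted over the list alone. Dbp, a clock output factor chosen here after its values were seen, was between 49.4 and 69.8 CPM in knockout replicates 1 to 4, 7.16 CPM in replicate 5 and between 4.26 and 9.18 CPM in Pparafl/fl. Npas2, a partner of the clock factor Arntl and chosen in the same way, was between 2.33 and 5.54 CPM in replicates 1 to 4, 33.0 CPM in replicate 5 and between 21.2 and 36.1 CPM in Pparafl/fl. The clock list's median log2 fold change was 0.57 with an adjusted p of 0.004, and an adjusted p = 0.12 with an estimated correlation.

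**Figure D4:**
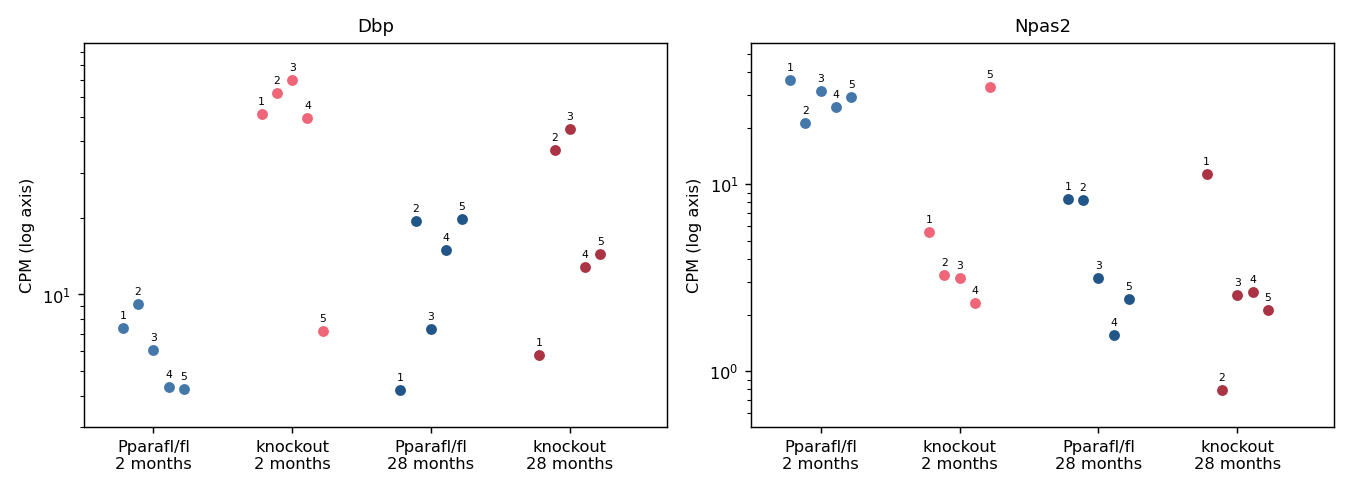
Dbp (left) and Npas2 (right) in CPM (log axes) in each of the 20 libraries, numbered by replicate. At 2 months knockout replicate 5 lay at 7.16 CPM of Dbp, inside the Pparafl/fl range of 4.26 to 9.18 CPM, and replicates 1 to 4 lay above it.

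Of 20 macrophage markers none passed over all genes and 7 were lower adjusted over the list alone, with a median log2 fold change of -0.50. Lyz2 averaged 334 ± 87.9 CPM (SD, n = 5) in the knockout and 586 ± 127 CPM (SD, n = 5) in Pparafl/fl, with an adjusted p of 0.296. Of 28 senescence and secretory genes 7 were lower adjusted over the list alone, of 19 antigen presentation genes 3 were lower, and of 24 antioxidant genes 2 were lower. Of 18 endothelial markers 5 were higher adjusted over the list alone, with a median of 0.42. Of 32 matrix genes 1 was higher and 1 lower adjusted over the list alone, with a median of -0.47, and no contractile gene passed, with a median of -0.44. The contractile list mean was 7.85 and 8.32 log2 CPM in knockout replicates 1 and 5 and between 6.06 and 6.49 in replicates 2 to 4. No member passed in either way in the other 9 called lists, whose medians were -1.06 for B and plasma cells, -0.98 for T and NK cells, -0.40 for the cell cycle, -0.31 for matrix proteases, -0.30 for interferon response, -0.25 for fibroblasts, 0.71 for Schwann cells and neurons, 1.04 for cardiomyocytes and 1.12 for skeletal muscle. The B and plasma cell mean was -0.24, -0.16 and 2.51 log2 CPM in knockout replicates 1, 4 and 5. Replicates 2 and 3, at 4.12 and 4.48, lay inside the Pparafl/fl range of 3.60 to 4.94. With an estimated correlation none of the 17 calls held. The adjusted p was 0.12 for the macrophage and senescence lists, 0.379 for the endothelial, T and NK cell, B and plasma cell and Schwann lists, and 0.417 for antigen presentation. It was 0.47 for the antioxidant and cell cycle lists, 0.482 for interferon, 0.497 for the matrix and protease lists, 0.559 for fibroblasts, 0.667 for the contractile and skeletal muscle lists and 0.707 for cardiomyocytes. The PPARα target list was not called, with a median log2 fold change of -0.07 and an adjusted p of 0.462, and the brown adipocyte and cholesterol medians of 0.11 and 0.06 were opposite in sign to their tests.

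Over all 20598 genes tested, edgeR called 0 higher and 1 lower, and 2081 had an unadjusted p under 0.05 where chance gives 1030. The 1 gene falls outside the rule for named genes and is given because the count is 1. It is Gm2541, a single-exon processed pseudogene on chromosome 16 (85553233 to 85553943), at 0 counts in all 5 young knockout libraries and 3.54 ± 0.553 CPM (SD, n = 5) in Pparafl/fl, at least 355-fold lower against a floor of 3 counts over the group. It was also at 0 in 2 of the 5 Pparafl/fl libraries at 28 months. In the knockout at 28 months it was at 118 to 339 counts, with 0 libraries at 0, so its absence did not follow the genotype. DESeq2 called 282 higher and 173 lower. The animal number of knockout replicate 5 lies among those of the Pparafl/fl mice, and those of replicates 1 to 4 form a separate run, so genotype and litter or day cannot be told apart from the files. Without knockout replicate 5, edgeR called 70 higher and 32 lower, and without Pparafl/fl replicates 1 or 4 it called 0 lower. Gm2541, itself single-exon, is removed by construction where single-exon and unevenly counted genes are left out. The fit of all 20 libraries called 1 gene, but not Gm2541.

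The genotype comparison at 28 months asks the same of the aged aorta. Skeletal muscle markers were lower in the knockout in 20 of 20 members. None passed over all genes and 17 were lower adjusted over the list alone. The estimated correlation between members was 0.717, so they did not vary independently. The list mean also varied widely within a group, between 0.04 and 6.12 log2 CPM in Pparafl/fl at 2 months. Muscle taken along with the aorta cannot be told apart from the genotype here. Neb, the giant filament protein nebulin, averaged 588 ± 468 CPM (SD, n = 5) in the knockout and 2959 ± 2261 CPM (SD, n = 5) in Pparafl/fl, with an adjusted p of 1. The list's median log2 fold change was -2.24, with an adjusted p of 2.15e-33, and an adjusted p = 0.205 with an estimated correlation.

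In the other called lists no member passed in either way. The medians were -0.42 for 32 oxidative phosphorylation genes, -0.39 for 35 PPARα target genes, 0.32 for 19 antigen presentation genes, 0.28 for 18 endothelial markers and 0.51 for 18 Schwann and neuronal markers. With an estimated correlation each had an adjusted p = 0.888. Cd36, a fatty acid carrier and PPARα target, averaged 1868 ± 453 CPM (SD, n = 5) in the knockout and 1707 ± 610 CPM (SD, n = 5) in Pparafl/fl. The lists not called had adjusted p between 0.0514 and 0.863, and the matrix protease median of 0.08 was opposite in sign to its test. Of 21468 genes tested edgeR called 0 higher and 0 lower, and 689 had an unadjusted p under 0.05 where chance gives 1073. DESeq2 called 106 higher and 119 lower. In data simulated at this spread, edgeR found 38.4% of genes changed 4-fold and 2% of those changed 2-fold, so changes of that size were often missed with 5 libraries per group.

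The interaction asks whether the age effect differs between the genotypes, with a positive value where the change with age was higher in the knockout. No gene passed in edgeR, with 0 higher and 0 lower of 23624 tested, 1432 at an unadjusted p under 0.05 where chance gives 1181, and 244 higher and 272 lower by DESeq2. Ppara had a log2 interaction of 0.47 with a standard error of 0.42. Skeletal muscle markers had a median of -3.33, with 1 of 20 lower adjusted over the list alone, and B and plasma cell markers a median of 1.84 with 22 of 22 members positive and none past the test in either way. In the young knockout the B and plasma cell mean lay below the young Pparafl/fl range only in replicates 1, 4 and 5. Macrophage markers had a median of 0.59 and senescence genes of 0.41, each with 2 members higher adjusted over the list alone. The clock list had a median of -0.77. Its median genotype effect was 0.57 at 2 months and -0.10 at 28 months, so a difference in collection at 2 months would enter it. In all 8 lists were called higher and 4 lower with the preset correlation, and none with an estimated one: the smallest was adjusted p = 0.101 for the clock list, and adjusted p = 0.281 for the skeletal muscle, B cell, macrophage, senescence and antigen presentation lists. It was 0.496 for interferon response (median 0.48), 0.551 for T and NK cells (0.90) and cardiomyocytes (-1.16), 0.576 for the matrix list (0.39), and 0.726 for the cell cycle (0.74) and oxidative phosphorylation (-0.48). The PPARα target list had a median of -0.23 and an adjusted p of 0.341.

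Age effects in the 2 genotypes, which share no library, ran alike: across 20174 genes Pearson's r was 0.633 and Spearman's rho 0.575, where genes are not independent replicates. Among genes called in both, 91 rose in both against 7.7 expected by chance, 140 fell in both against 13.7 expected, and 0 moved in opposite directions. A tissue mix that differs with age in both genotypes would enter this agreement too, and cannot be told apart from age here. Matrix genes fell in each genotype, 26 of 32 in Pparafl/fl and 21 of 32 in the knockout, where the list had an adjusted p = 0.167 with an estimated correlation. The genotype effects at the 2 ages had r = 0.027 and rho = 0.046 across 19899 genes. The genotype effect at 2 months and the age effect in Pparafl/fl share the young Pparafl/fl libraries, and across 22246 genes their r was 0.366. Simulations with each group unchanged, in which the simulated young Pparafl/fl libraries were shared in the same way, gave a mean r of 0.499, above the observed one. The covariance went the other way, at 0.299 observed against a mean of 0.2 and a highest value of 0.213 in the simulations. Splitting the shared libraries into 2 and 3 gave a mean r of 0.118 and a mean covariance of 0.12 over 20 splits.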

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

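The tests of scaling, of airway tissue in place of aorta, of a lower share of smooth muscle cells, of another tissue mix and of the hour or day of collection were chosen only after the result was seen. Of 543 groups of 5 libraries tested, 37 held a library far from the other 4, where chance flags about 1 in 20 groups, 27.1 here.

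Smooth muscle and matrix genes were lower at 28 months in both genotypes, though in the knockout both list calls were lost with an estimated correlation (adjusted p = 0.362 and 0.167). Scaling as the whole cause is argued against, since a factor for a whole library cancels in a list mean minus the median of all genes of that library. On unscaled counts that difference changed with age by -2.4 and -1.91 log2 units for matrix genes and by -2.2 and -1.75 for contractile genes in Pparafl/fl and the knockout, against SDs of at most 1.08. Argued against too is airway tissue in place of aorta, since the 2 aged libraries with Scgb1a1 under 1 CPM had contractile means of at most 4.96 log2 CPM against at least 7.20 in young Pparafl/fl. One of them, Pparafl/fl replicate 5, still held some airway RNA (airway mean 1.19), and the other had an airway mean of -0.73. With the airway mean as a covariate the contractile median was -2.97 in Pparafl/fl and -2.20 in the knockout. These adjusted medians decide little, since in Pparafl/fl the airway mean was at most -0.83 at 2 months and at least 1.19 at 28 months. In the knockout the ages overlapped only through replicate 1 at 2 months and replicate 5 at 28 months. A lower share of smooth muscle cells alone is not decided in either genotype. In Pparafl/fl skeletal muscle and fibroblast marker medians moved apart by 4.67 against an SD of 2.63. That test was written after its result was seen, and both list calls were lost with an estimated correlation (adjusted p = 0.265 and 0.097). The skeletal muscle mean also ran from 0.04 to 6.12 log2 CPM within Pparafl/fl at 2 months. In the knockout skeletal muscle and fibroblast medians moved apart by 1.52, within an SD of 2.89. Macrophage and fibroblast medians moved apart by 1.99 against an SD of 0.58. Macrophage markers were taken up only after the first result was seen, so they cannot decide, and a rise in macrophages themselves stays open. Another mix of wall, fat, muscle and airway in the tissue taken cannot be told apart from age, since the young knockout libraries alone span 2.26 log2 units in the contractile mean and no library separates them. Age itself, which the design names, may act on these genes and stays open, untested apart from the tissue mix.

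Clock genes differed between the genotypes at 2 months in knockout replicates 1 to 4, though no clock gene passed over all genes and the list call was lost with an estimated correlation (adjusted p = 0.12). With the contractile mean as a covariate the clock median was 0.64, against 0.57 without it, so the covariate did not make it smaller. Its adjusted p of 0.0362 is at the preset correlation, where other splits of these libraries called a median of 12 lists. Whether a lower share of smooth muscle in some knockout libraries contributes is therefore not decided. Knockout replicate 5, with an animal number among those of the Pparafl/fl mice, lay inside the Pparafl/fl range in 15 of 19 clock genes, so another hour or day of tissue collection may contribute. In 1 of the 10 genes that set replicates 1 to 4 apart, Nr1d1, it lay with them at 146 CPM against at most 123 CPM in Pparafl/fl, and in 8 it lay inside the Pparafl/fl range. That is 1 library, so collection and genotype cannot be told apart. An effect of the genotype on the clock stays open, as untested.

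Airway genes were most abundant in the 9 libraries with Scgb1a1 above 1 CPM, with airway means of 1.91 log2 CPM or more, and Pparafl/fl replicate 5 at 28 months held them at a lower level (1.19). If airway tissue was collected with the aorta, genes of ciliated cells should be there too, and their mean lay above that of each other library in 9 of 9, at 1.05 or more against 0.09 or less over 6 genes. This is consistent with airway tissue in those samples as a hypothesis. No biological explanation was tested.

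Among the 20 libraries, knockout replicate 1 at 2 months lay above the other 4 in the airway mean (2.30 log2 CPM), Bpifa1 (6.29), Cyp2a5 (3.56) and Spag17 (0.564), and below them in B2m (8.95). Knockout replicate 5 at 28 months lay below the others in the airway mean (-0.73), A2ml1 (-1.29), Bpifa1 (-1.74), Cyp2a5 (-4.96), Spag17 (-4.96) and Ctsk (2.40). Knockout replicate 4 at 28 months lay below in the fibroblast mean (4.44), Col1a1 (5.08) and Prdm16 (3.31) and above in Ighg2c (11.8), and replicate 1 lay below in Timp3 (6.56) and above in Prnd (-3.99). A value of -4.96 stands for 0 counts. Prnd was at only 0.0308 CPM in that replicate and at 0 in the other 4, where any count is flagged. The same holds for Spag17 in the knockout at 2 months. Knockout replicate 5 at 2 months lay above in Clock (7.54), Col1a1 (10.4) and Csf1r (7.52), replicate 4 above in Ndufb8 (8.09) and replicate 2 below in Igfbp5 (5.44).

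In Pparafl/fl at 2 months, replicate 1 lay above the others in Hbb-bs (8.55 log2 CPM) and Mblac1 (2.38) and below in Ifi27l2a (6.96), and replicate 2 lay above in Olfr1034 (2.69) and Pck1 (12.5). At 28 months, replicate 1 lay above in Ndufa4 (7.87) and below in Tubb3 (5.73), replicate 2 above in Prnd (1.15) and below in Mblac1 (-4.96), and replicate 4 below in Map3k7cl (-1.83) and Olfr1034 (-4.96). For Mblac1 and Olfr1034 at 2 months and Prnd at 28 months, the other libraries of the group were at 0 counts, where any count is flagged. Replicate 3 at 28 months lay below in Ppara (4.69) and above in total counts (71.2, in units of 1e6) and in the mitochondrial share of counts (7.55%), most of it from mt-Co1, a single-exon gene at 0 or 1 count in 19 libraries and at 5083625 counts in that one, so the share reflects uneven counting. Knockout replicate 3 at 28 months lay above in that share (0.907%).

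The age effect differed between the genotypes, by the interaction test with the preset correlation, in 12 lists. None held with an estimated correlation, where the smallest adjusted p was 0.101, and 21 of 60 splits of the libraries, the real one included, called as many, so the difference is not established. The median log2 interactions were 0.39 for matrix genes, 0.41 for senescence, 0.74 for the cell cycle, 0.48 for interferon response, 0.95 for antigen presentation and -0.77 for the clock. They were -0.48 for oxidative phosphorylation, 0.59 for macrophages, 0.90 for T and NK cells, 1.84 for B and plasma cells, -3.33 for skeletal muscle and -1.16 for cardiomyocytes.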

How the results depend on the processing

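Gene lists, comparisons and the first set of other settings were set before the data were examined; the airway, skeletal muscle, clock and contractile covariates, the fit without single-exon and unevenly counted genes and the fit without 9 libraries with Scgb1a1 above 1 CPM were chosen only after the result was seen. With DESeq2 size factors, a mean of at least 50 counts or a 2-fold minimum, each count of genes stayed within 1.5 times its value, and with size factors 941 of the 953 genes called for age in Pparafl/fl and 904 of the 934 in the knockout were shared.

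Age in Pparafl/fl gave 1977 higher and 1341 lower with the DESeq2 Wald test, which made more false calls in simulated data. It gave 214 and 347 with no filter (more genes tested), 63 and 140 with the adipocyte covariate, 6 and 38 with the airway covariate, 1 and 5 with the skeletal muscle covariate and 15 and 25 without the 9 libraries. Ppara had a log2 fold change of -1.01 with an adjusted p of 0.0399 with the Wald test. Age in the knockout gave 1911 and 1530 with the Wald test, 166 and 315 with no filter, 743 higher in 1 fit of 20 libraries, 8 and 2 with the adipocyte covariate, 0 and 1 with the airway covariate, 50 and 103 with the skeletal muscle covariate and 7 and 9 without the 9 libraries. The 0 came from edgeR, with 2047 genes of either direction at an unadjusted p under 0.05. The fit without 9 libraries leaves 1 library per genotype at 28 months, assumed to vary like the other groups. Of 33 named genes called in Pparafl/fl, 20 lost the call with the adipocyte, 26 with the airway and 31 with the skeletal muscle covariate, and of 36 in the knockout 34, 36 and 19 did. Without the 9 libraries 32 of the 32 tested in Pparafl/fl and 35 of the 36 in the knockout did, none with a reversed sign. Beyond fewer samples or more genes, the cause was not tested.

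Contractile and matrix medians stayed below 0 under each of these covariates: contractile -2.53, -2.97 and -1.56 in Pparafl/fl and -2.02, -2.20 and -1.14 in the knockout with the adipocyte, airway and skeletal muscle covariates. In Pparafl/fl neither the airway nor the skeletal muscle means of the 2 ages overlapped, so medians adjusted for them decide little.

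The genotype effect at 2 months gave 282 higher and 173 lower with the Wald test, 2 lower with the adipocyte covariate, and 0 lower with the airway, clock and contractile covariates. Without single-exon and unevenly counted genes it gave 0 lower by construction, since the gene called is itself single-exon. At 28 months it gave 106 and 119 with the Wald test and 12 and 5 without the 9 libraries. The interaction gave 244 and 272 with the Wald test and 12 and 4 without the 9 libraries. Apart from the filter on single-exon genes, the cause was not tested. The correlation between genotype and age effects that share the young Pparafl/fl libraries was 0.366, and 0.118 with those libraries split, which removes the sharing.

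With an estimated correlation 0 lists were higher and 3 lower for age in Pparafl/fl, and 0 and 0 in each other comparison. For age in Pparafl/fl 4 lists were higher and 6 lower with the adipocyte covariate and 5 higher with the airway covariate. At 28 months 1 list was higher without the 9 libraries and 6 were lower with the skeletal muscle covariate. For the interaction 5 were higher with the clock covariate and 4 without the 9 libraries.

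Several list medians reversed, or their test did, and the cause was not tested. For age in Pparafl/fl these were, with the airway covariate, interferon 0.25, antigen presentation 0.62, cardiomyocytes -2.34 and mesothelium -1.25. Without the 9 libraries they were interferon -0.01 (the test upward) and antigen presentation 0.12, and with the adipocyte covariate antigen presentation 0.15 and oxidative phosphorylation 0.06. For the genotype at 2 months with the clock covariate they were contractile 0.34, matrix 0.22, proteases 0.17, antioxidant 0.14, fibroblasts 0.24, skeletal muscle -4.04 and cardiomyocytes -2.14. Each gene of that covariate set knockout replicates 1 to 4 apart from Pparafl/fl, so the covariate lies close to the genotype itself. The adjusted effect then leans on knockout replicate 5, and these reversals decide little. At 28 months without the 9 libraries interferon was -0.36 and antigen presentation -0.25. For the interaction the cell cycle was -0.47 with the clock covariate and interferon -0.03 without the 9 libraries. A list set against its own mean is fixed by construction: skeletal muscle was -0.36 for age in Pparafl/fl and -0.01 for the genotype at 2 months, and contractile -0.02 there.

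Leaving out 1 library gave, for age in Pparafl/fl, between 132 and 1019 higher, between 231 and 1275 lower, between 2 and 4 lists higher (4 without replicate 3 of either age) and between 9 and 12 lower, with Ppara between -1.15 and -0.82. For age in the knockout it gave between 89 and 478 higher, between 146 and 479 lower, between 4 and 7 lists higher and between 8 and 9 lower, with Ppara between -0.69 and -0.44. For the genotype at 2 months it gave between 0 and 70 higher and between 0 and 32 lower, both highest without knockout replicate 5, between 4 and 6 lists higher and between 9 and 13 lower, with Ppara between -0.47 and -0.18. The other changes were 2 higher without Pparafl/fl replicate 2, 1 higher without Pparafl/fl replicate 5 or knockout replicate 2, 3 lower without Pparafl/fl replicate 3, 2 lower without knockout replicates 2 or 3 and 0 lower without Pparafl/fl replicates 1 or 4.

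At 28 months leaving out 1 library gave between 0 and 1 higher (1 without Pparafl/fl replicates 2 or 3 or knockout replicate 1), between 0 and 1 lower (1 without Pparafl/fl replicate 5 or knockout replicates 1, 2 or 3), and Ppara between -0.09 and 0.23. Between 1 and 6 lists were higher, with 1 without Pparafl/fl replicate 3, 5 without Pparafl/fl replicates 2 or 5 or knockout replicate 2, and 6 without knockout replicate 3. Between 3 and 6 were lower, with 5 without Pparafl/fl replicates 3 or 5 or knockout replicate 2, and 6 without knockout replicate 3. The oxidative phosphorylation median lay between -0.61 and 0.02, the last without Pparafl/fl replicate 1, and the endothelial median between 0.14 and 0.41, its test downward at 0.21 without knockout replicate 2. For the interaction leaving out 1 library gave between 0 and 1 higher (1 without young Pparafl/fl replicate 2), 0 lower, between 7 and 12 lists higher and between 3 and 6 lower, with Ppara between 0.26 and 0.60. No term for sex was run, since the files show no library of the other sex, and no pseudocount alternative applied. With 5 libraries per group, edgeR found between 2% and 17% of simulated 2-fold changes, which limits what was detectable.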

Other observations

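The fit without 9 libraries and the airway list were chosen only after the result was seen. Other splits of the same libraries were counted for each comparison. For the age effect in Pparafl/fl, 1 of 100 splits, the real one, called as many as 953 genes, the highest of the others calling 6. For age in the knockout 1 of 100 did, with 934 against 126, so a chance division of the libraries is an unlikely source of these counts. The other splits mix the ages, and they say nothing about tissue or collection that differ with age. For the genotype at 2 months 54 of 100 splits called at least the real 1 gene, the highest calling 92, which points to a structure of the samples. Chance is not excluded for that count. At 28 months and for the interaction the real count is 0, which every split reaches (100 of 100 and 60 of 60), so these splits decide nothing. The highest of the others called 12 and 2.

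For the gene lists at the preset correlation chance is not excluded in any comparison. As many lists as the real 12 were called in 40 of 100 splits for age in Pparafl/fl, with 16 as the highest of the others, and as many as the real 13 in 41 of 100 for age in the knockout, with 20. For the genotype at 2 months 10 of 100 splits called as many as the real 17, with 20 as the highest, and at 28 months 94 of 100 called as many as the real 6, with 18. For the interaction 21 of 60 splits called as many as the real 12, with 17.

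Sost was between 61.4 and 194 CPM in the young Pparafl/fl libraries, at 85.2, 4.37, 6.24, 0.496 and 252 CPM in young knockout replicates 1 to 5, and at most 1.04 CPM in each library at 28 months. The mean of T and NK cell markers was -1.15, 3.39, 3.36, -0.05 and 1.45 log2 CPM in young knockout replicates 1 to 5, and between 3.22 and 3.61 in young Pparafl/fl.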
